A study of Homo sapiens with 45 samples.

How the data were processed

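The 45 arrays came from A2780 cells in 18 groups, 3 treatments at 6 hours, with 2 or 3 arrays per group. Per the labels, cells were grown in RPMI medium with fetal bovine serum, plated the day before exposure, and RNA was extracted with RNeasy columns, amplified from the 3' end in 1 cycle and labelled with biotin for Affymetrix whole-genome arrays. The deposited values are intensity on a linear scale, made by the authors with RMA and rounded to 3 significant digits, and the analysis here took their log2 without a pseudocount. The version of RMA, the scanner settings and the probe-level files' processing parameters were not given in the sources used here. The tables held 54675 probe sets with 0 missing values, and all per-sample value columns were used. The intensity ran from 0.463 to 22000. The precision at each hour was set by 2 or 3 arrays per group, and single-hour tests therefore miss smaller changes more often than tests over all hours.

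Groups, hours and hybridisation days were read from the labels, and no sample was left unassigned. Of the probe sets, 41097 carried 1 gene symbol, 1801 several and 11777 none, and 62 were control probe sets. Symbols were matched to RefSeq gene identifiers for 41043 probe sets, and the genome table was used for names only. For each of 19775 genes the probe set with the highest mean was tested, and 10523 genes had more than 1. Probe sets with several symbols or none were left out of the gene tests and entered only the alternative over all probe sets.

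Tests were run in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Group means adjusted for hybridisation day were fitted with hour and compound terms, which gave compound A against untreated, compound B against untreated and compound A against compound B over 6 hours. All 3 treatments shared 1 estimate of the spread. Changes over time in the effect of compound A enter it and widen the errors for compound B. The same means gave the difference between the last and first 3 hours and the slope per hour in untreated cells. Single-hour contrasts and the F test of the day used all 45 arrays with group and day terms. P-values were two-sided and adjusted by the Benjamini and Hochberg method, with a threshold of 0.05. Without any change a share of about 0.05 of the genes would have an unadjusted p under 0.05. Unadjusted counts, given beside 0 calls, are to be read against that share. Gene lists written by hand, 27 in number and each with at least 5 measured genes, were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated one, and adjusted over 81 tests. List tests of the difference between the first and last 3 hours, for each compound against untreated cells, were adjusted over 54 tests. The lists were p53 targets, immediate early genes, ERK feedback genes, short-lived transcripts, G1/S and E2F targets, G2/M mitotic genes, histone genes, the ATF4 pathway, ER chaperones, heat shock genes, NRF2 targets, NF-kB targets, cholesterol genes, hypoxia targets, FOXO and PI3K-responsive genes, ribosome biogenesis genes, interferon-stimulated genes, metallothioneins, TGF-beta targets, Wnt and YAP targets, apoptosis regulators, CDKs and cyclins, housekeeping genes, and markers of fibroblasts, haematopoietic cells, endothelium and ovarian surface and Mullerian epithelium.

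The groups, comparisons, tests, alternative settings and the rule for naming genes were fixed before the data were examined. By that rule each comparison over all hours named the 8 largest rises and falls among calls with the same sign at each of 6 hours, and up to 3 members with the smallest p of each list that passed and of the p53, E2F, mitotic, immediate early and ATF4 lists in any case. The comparisons between the first and last 3 hours and the slope named the 4 highest and 4 lowest calls, each compound at 1 and 6 h the 3 highest and 3 lowest, and the day test the 4 largest F values. Where fewer passed all were named, and where none passed the 2 with the smallest p. ACTB, GAPDH and the control probe sets were added, and a gene whose other probe sets moved the opposite way was named with that fact.

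Alternative settings chosen at that time were no day adjustment, single arrays with the group as a random block, weighting by array number, an intensity trend with a robust prior, brighter genes only, all probe sets, the mean of a gene's probe sets, repeated quantile normalization, median centring (not at single hours), leaving out each hour or array, a replicate block, single hybridisation days, other day terms at single hours, and estimated correlation for lists. Alternatives added after the data were examined were leaving out 3 compound B arrays, leaving out 4 and 5 h, median centring at single hours, and scaling to 24 poly-A or 18 hybridisation spike-in probe sets. Rises and falls of brighter and dimmer genes were also counted under each scaling. Fits within single hybridisation days took single arrays as the repeats, unlike the fits of 18 group means, so their counts are not on an equal footing. The spike-ins were compared by exact sign-flip tests over 6 hours. Random regroupings were drawn 100 times for comparisons over all hours and for the day, and the 10 possible splits were used for 3 against 3. Random gene lists matched for brightness were drawn 1000 times.

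The procedure was tested on simulated data of 19775 genes. Hour-to-hour spread was taken from untreated cells and compound B only, and the change seeded over 6 hours was equal at all hours. In the real data time-dependent effects of compound A add to the shared spread. Recovery in the fits of group means may therefore be lower there than in the simulation. With 200 changed genes the comparison over 6 hours made 207 calls, 8 of them false, and recovered 98.5% of changes of 0.5 and 100% of changes of 1 on the log2 scale. At 6 h it made 207 calls, 37 of them false, and recovered 55.9% and 100%, and at 4 h 176 calls, 24 of them false, with 32.4% and 97.0%. The false calls at single hours came from group-to-group spread that was put into the simulation and that arrays of a group do not show. With no change it made 0 calls over 6 hours and 5 at 6 h. The day test made 202 calls, 6 of them false, and the comparison of first and last 3 hours recovered 58.8% of differences of 0.5 and 98.5% of differences of 1. Slopes of 0.1 and 0.2 were recovered in 41.8% and 100% of genes, and 1 list shifted by -0.3 was called with 0 other lists called. One control measurement of RNA integrity is not reported here.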

Results

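Transcript levels were measured in A2780, a human ovarian cancer cell line, left untreated or exposed to 1 of 2 compounds known only by code names and called compound A and compound B here. RNA was collected every hour from 1 to 6 h and hybridised to 45 Affymetrix expression arrays of 54675 probe sets. Untreated cells, compound A and compound B had 15 arrays each, with 3 arrays per group at 1, 3 and 6 h and 2 arrays per group at 2, 4 and 5 h. The series evaluated the effect of the hybridisation day, and its arrays were spread over 4 days, called A to D here, of 7, 9, 11 and 18 arrays. Treatments were unevenly spread over the days, with 1 untreated array on day B and 8 on day D. The design text describes the arrays of a group as technical repeats, so p-values at a single hour measure only the spread between arrays. Comparisons over all hours used the 18 group means, with the 6 hours as the repeated measurements of a treatment. The labels do not say which hours or arrays came from separate cultures. P-values over the 6 hours, those of the spike-ins included, are therefore not known to cover the spread between cultures. Array medians of the intensity lay between 26.1 and 28.6 and upper quartiles between 111 and 140. Group means of the upper quartile were 129.8 at 1 h and 111.3 at 6 h under compound A. In untreated cells they were 131 and 132.7, and the highest array, at 140, was a compound B array at 4 h. The 36 pairs of arrays within a group had correlations across genes from 0.974 to 0.998, and the SD of their log2 differences ran from 0.16 to 0.61, which together with the small number of arrays limits the precision.

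Compound A was first compared with untreated cells over all 6 hours, to see which transcripts it changed at matched times. Its deepest falls included DUSP1, which encodes a phosphatase that inactivates MAP kinases, NFIL3, a transcriptional repressor, and the zinc-finger genes ZNF256, ZNF92 and ZNF670. ZNF256 fell by 3.32 ± 0.23 on the log2 scale (SE, n = 6 hours, limma adjusted p = 9.71e-07), from 7.60 ± 0.15 in untreated cells to 4.29 ± 0.94 (mean ± SD of 6 hours). DUSP1 fell by 3.17 ± 0.19 (SE, limma adjusted p = 2.73e-07), although 1 of its 2 other probe sets moved the opposite way. ZNF92 changed by -3.25, ZNF670 and NFIL3 by -3.001 each and the exocyst gene EXOC8 by -3.003. The nuclear receptor coactivator PNRC1 and the chromatin gene MSL2 changed by -3.01 each. The largest rises were in AMDHD1, an enzyme of histidine breakdown, the histone genes H2AC8 and H3C2, C1orf162, the neuroendocrine chaperone SCG5, and the noncoding transcripts RFPL3S, LINC00326 and BCAR4. AMDHD1 rose by 2.17 ± 0.47 (SE, limma adjusted p = 0.00261), from a difference of 0.30 at 1 h to 4.22 at 6 h. H2AC8 rose by 2.13 ± 0.40 (SE, limma adjusted p = 0.00109), C1orf162 by 1.90, RFPL3S by 1.75, SCG5 by 1.47, H3C2 by 1.46, LINC00326 by 1.45 and BCAR4 by 1.21.

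Of the 19775 genes tested, 10716 passed an adjusted p of 0.05 under compound A, 7238 of them higher and 3478 lower. The falls were deeper than the rises, with a median log2 change of -0.58 among lower genes and 0.23 among higher genes, and 844 genes fell but 13 rose more than 2-fold. The control genes ACTB and GAPDH changed by -0.04 ± 0.04 and 0.03 ± 0.03 (SE, limma adjusted p = 0.318 and 0.495). The balance of rises and falls depended on the scaling. As deposited, 67.5% of the called genes were higher and the median over all genes was 0.10. The share of rises was 56.1% with arrays centred on their median, 3.26% with arrays scaled to the hybridisation spike-ins and 0.175% with arrays scaled to the poly-A spike-ins, and the median over all genes moved to 0.06, -0.12 and -0.43. The poly-A spike-ins, bacterial RNAs added before labelling, read 0.48 higher in the compound A groups, in 6 of 6 hours, and 0.46 and 0.34 higher within hybridisation days C and D. Within days C and D alone 3634 and 3210 genes passed, in fits that took single arrays as the repeats. The log2 changes on those days correlated with those over all days at 0.979 and 0.916 across genes, which are not independent replicates. The arrays of each day also enter the values over all days, so a high correlation is partly built in and is no replication. Days A and B held too few matched hours for a value. Without the 4 and 5 h groups 4425 genes passed.

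**Figure D1:**
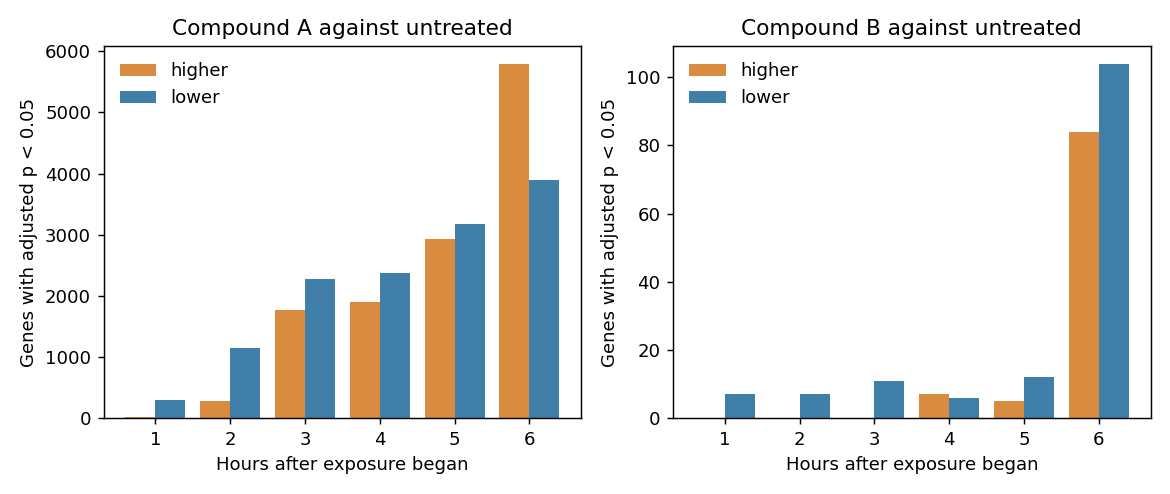
Number of genes with an adjusted p under 0.05 at each hour against untreated cells (y axes, linear, different ranges), for compound A (left) and compound B (right), with higher and lower genes as separate bars. Compound A calls rose from 324 at 1 h to 9687 at 6 h and compound B calls from 7 to 188, and the split into higher and lower genes holds for the values as deposited, since with poly-A scaling 30 genes were higher and 15955 lower at 6 h under compound A.

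Transcripts with a fast turnover were the most uniformly lowered group under compound A. All 32 measured members of the list of short-lived transcripts fell (camera adjusted p = 1.42e-25, adjusted p = 0.0136 with an estimated correlation). Among them were ID1, an inhibitor of basic helix-loop-helix factors, which fell by 2.36 ± 0.14 (SE), BHLHE40, a circadian repressor, which fell by 2.55 ± 0.16, and MYC, a growth-promoting transcription factor, which fell by 1.93 ± 0.13. Of 27 immediate early genes, which are switched on within minutes by growth factors, 22 fell, 1 rose and 4 did not pass (camera adjusted p = 1.97e-15, adjusted p = 0.0595 with an estimated correlation). TRIB1, a pseudokinase gene, fell by 2.97 ± 0.17 beside DUSP1 and MYC. Of 17 genes transcribed downstream of ERK and feeding back on it, 12 fell, 2 rose and 3 did not pass, with 12 falls and 3 rises adjusted over the list alone (camera adjusted p = 3.22e-06, adjusted p = 0.0339 with an estimated correlation). SPRY1, an inhibitor of receptor tyrosine kinase signalling, fell by 2.11 ± 0.13. The ERK phosphatase DUSP5 fell by 1.94 ± 0.14 and the receptor EPHA2 fell by 0.69 ± 0.06. Within hybridisation days C and D the mean log2 change was -1.49 and -1.45 for the short-lived transcripts, -1.03 and -1.40 for the immediate early genes and -0.60 and -0.74 for the ERK feedback genes.

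Lists of TGF-beta, Wnt and YAP, hypoxia and FOXO targets also passed in the downward direction under compound A. Among 17 TGF-beta and SMAD targets 11 fell and 4 rose (camera adjusted p = 1.5e-06, adjusted p = 0.0683 with an estimated correlation), with ID1, BHLHE40 and the SMAD corepressor TGIF1, which fell by 2.24 ± 0.16 (SE), at the front. Among 16 Wnt and YAP targets 10 fell and 2 rose (camera adjusted p = 2.01e-05, adjusted p = 0.0186 with an estimated correlation). They included CCN2, a matricellular protein gene induced by YAP and TGF-beta, which fell by 2.18 ± 0.16, and AXIN2 and ZNRF3, both negative regulators of Wnt signalling, which fell by 0.92 ± 0.09 and 0.75 ± 0.08. Among 19 hypoxia targets, with a median of -0.02, 7 fell and 4 rose (camera adjusted p = 0.0133, adjusted p = 0.0803 with an estimated correlation), led by the peptide hormone gene ADM with a fall of 2.08 ± 0.15, ANKRD37 with 1.22 ± 0.13 and the angiogenic factor VEGFA with 0.73 ± 0.06. Of 22 FOXO and PI3K-responsive genes 8 fell and 3 rose (camera adjusted p = 0.0125, adjusted p = 0.105 with an estimated correlation), with a list mean of -0.38 and a median of 0.00. CITED2, a transcriptional coregulator, fell by 2.47 ± 0.16, with 1 of its 2 other probe sets opposite. The repressor BCL6 fell by 1.88 ± 0.23 and the CDK inhibitor CDKN1B fell by 0.83 ± 0.13. For these 4 lists the counts adjusted over the list alone were equal to those over all genes.

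Lists of stress, p53, cell-cycle and ribosome biogenesis genes also passed in the downward direction under compound A. Of 31 genes of the ATF4 pathway, which responds to amino acid shortage and unfolded proteins, 19 fell and 5 rose, also when adjusted over the list alone (camera adjusted p = 9.25e-09, adjusted p = 0.0339 with an estimated correlation). DDIT4, an inhibitor of mTORC1, fell by 1.89 ± 0.08 (SE, limma adjusted p = 1.11e-08), the glutathione-degrading enzyme CHAC1 by 2.12 ± 0.15 and the transcription factor DDIT3 by 1.11 ± 0.08. Of 27 p53 targets 17 fell and 5 rose, with 18 falls adjusted over the list alone (camera adjusted p = 5.7e-06, adjusted p = 0.0817 with an estimated correlation). The kinase PLK2 fell by 2.92 ± 0.15, the secreted cytokine GDF15 by 1.33 ± 0.12 and the DNA polymerase gene REV3L by 0.90 ± 0.10. Of 33 G1/S and E2F targets 15 fell and 4 rose, with 16 falls adjusted over the list alone (camera adjusted p = 0.00173, adjusted p = 0.0823 with an estimated correlation), among them the cyclin CCNE2 by 1.05 ± 0.16, the uracil glycosylase UNG by 0.63 ± 0.08 and the licensing factor CDT1 by 0.27 ± 0.04. Of 42 mitotic genes 15 fell and 3 rose (camera adjusted p = 0.000294, adjusted p = 0.62 with an estimated correlation). The centromere chaperone HJURP fell by 1.48 ± 0.28 and the kinesin KIF23 by 0.98 ± 0.20, with its other probe set opposite. The survival gene BIRC5 rose by 0.21 ± 0.05 as deposited and changed by -0.32 with poly-A scaling and by -0.01 with hybridisation spike-in scaling. Of 24 CDK and cyclin genes 14 fell and 3 rose (camera adjusted p = 2.07e-05, adjusted p = 0.113 with an estimated correlation). CCNT2 and CCNT1, the cyclin partners of the elongation kinase CDK9, fell by 1.37 ± 0.16 and 0.40 ± 0.06. Of 25 ribosome biogenesis genes 10 fell and 2 rose (camera adjusted p = 0.000432, adjusted p = 0.212 with an estimated correlation). RRS1 fell by 0.90 ± 0.14, NOP2 by 0.57 ± 0.08 and TFB2M by 0.62 ± 0.11, for which 2 of 3 other probe sets were opposite.

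Histone genes were the single list with a passing test in the upward direction under compound A. No list passed upward among brighter genes only, with 3 h left out, or with 3 compound B arrays left out. Of 14 measured histone genes 10 rose, 1 fell and 3 did not pass as deposited, while 2 rose and 7 fell with poly-A scaling (camera adjusted p = 0.0383, adjusted p = 0.562 with an estimated correlation). Besides H2AC8, H1-2 and H2BC5 rose by 0.50 ± 0.08 and 0.46 ± 0.07 (SE) as deposited, and with poly-A scaling they changed by -0.03 and -0.07. Histone values here are array signals after amplification from the 3' end, and whether they follow histone transcript levels was not tested. The other 13 lists did not pass. In 17 genes of ER chaperones and XBP1 targets 6 rose and 4 fell (camera adjusted p = 0.938), in 16 heat shock genes 5 rose and 4 fell (adjusted p = 0.517), in 20 NRF2 targets 10 rose and 7 fell (adjusted p = 0.871), and in 19 NF-kB targets 2 rose and 5 fell (adjusted p = 0.0619). In 18 cholesterol and SREBP targets 8 rose and 5 fell (adjusted p = 0.586), in 18 interferon-stimulated genes 5 rose and 5 fell (adjusted p = 0.654), in 8 metallothionein genes 1 fell (adjusted p = 0.653), in 20 apoptosis regulators 6 rose and 7 fell (adjusted p = 0.224), and in 11 housekeeping genes 2 rose and 2 fell (adjusted p = 0.891). Among markers of other cell types, 6 of 12 fibroblast, 6 of 11 haematopoietic, 2 of 9 endothelial and 7 of 14 ovarian surface and Mullerian epithelial genes rose as deposited and none fell (camera adjusted p = 0.511, 0.224, 0.341 and 0.196). Adjusted over the list alone, 0 of the endothelial genes passed by limma.

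More genes passed under compound A at each later hour, although not under each setting, with 3043 at 3 h and 1278 at 4 h when only the groups of the hour were used, 5704 at 4 h and 5610 at 5 h without a day term, 3663 at 3 h and 3561 at 4 h with arrays centred on their median, 4541 at 3 h and 4414 at 4 h with quantile normalization repeated, and 11828 at 4 h and 4977 at 5 h with poly-A scaling. Immediate early genes had a mean of -1.50 at 1 h, -1.56 at 2 h and -0.61 at 6 h, and the difference between first and last 3 hours passed for the list with a fixed correlation (adjusted p = 0.00106) but not with an estimated one (0.755). At 1 h 324 genes passed, 302 of them lower, and the deepest falls were in EGR1 and FOS, immediate early transcription factors, and HES1, a Notch target. EGR1 fell by 4.37 ± 0.22 (SE, 3 arrays against 3, limma adjusted p = 4.55e-15), HES1 fell by 3.17 ± 0.15 and FOS fell by 3.01 ± 0.19. SRGAP2, the splicing kinase CLK1 and LHX4-AS1 rose by 1.41 ± 0.23, 1.14 ± 0.20 and 0.75 ± 0.12. At 6 h the deepest falls were in ZBED5, which fell by 5.34 ± 0.15 (limma adjusted p = 1.61e-21, 1 of 2 other probe sets opposite), the ER cochaperone DNAJB9 with -4.75 ± 0.19 and the mRNA cap methyltransferase CMTR2 with -4.73 ± 0.21. The highest rises were in AMDHD1, H2AC8 and C1orf162 with 4.22, 3.88 and 3.74. Of the 302 genes lower at 1 h, 252 were also lower and 8 were higher at 6 h. Calls numbered 1431 at 2 h, 4049 at 3 h, 4277 at 4 h, 6096 at 5 h and 9687 at 6 h, with 283, 1775, 1901, 2925 and 5798 genes higher. These p-values cover the spread between arrays only. Genes higher made up 43.8%, 44.4%, 48.0% and 59.9% of the calls from 3 to 6 h as deposited, 32.7%, 27.8%, 35.8% and 47.5% with arrays centred on their median, and 0.201%, 0.178%, 0.542% and 0.188% with poly-A scaling, and at 2 h 19.8% fell to 0.0664% with that scaling. Leaving out single arrays moved the counts most at 2 h, to 739 without compound A array 2 and 907 without untreated array 2, at 4 h, to 2235 without untreated array 1 and 2764 without compound A array 1, at 5 h, to 3630 without untreated array 1, at 3 h, to 2353 without compound A array 3, and at 1 h, to 202 without compound A array 2.

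**Figure D2:**
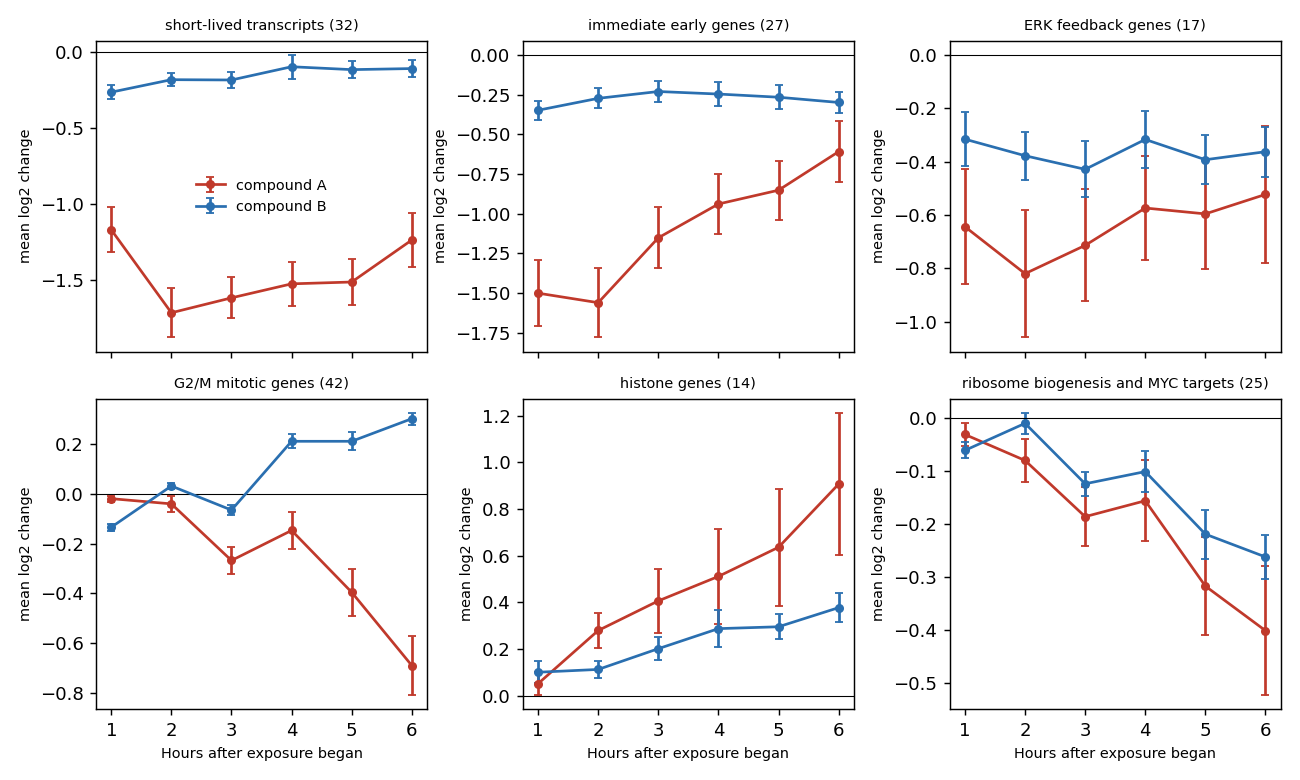
Mean log2 change against untreated cells at each hour (y axis) for 6 gene lists, with the number of measured genes in each title, for compound A (red) and compound B (blue), where bars are the SEM over genes and not over cultures. Short-lived transcripts averaged -1.17 at 1 h and -1.24 at 6 h under compound A, immediate early genes -1.50 and -0.61, and ERK feedback genes under compound B -0.32 and -0.36, while the upward lines of histone and mitotic genes hold for the values as deposited, their median under poly-A scaling being -0.22 for histone genes under compound A and -0.09 for mitotic genes under compound B.

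Between the first and last 3 hours, the effect of compound A on 2569 genes changed, upward in 615 and downward in 1954. ZBED5 went from -1.50 over 1 to 3 h to -4.45 over 4 to 6 h, a difference of -2.95 ± 0.56 (SE, limma adjusted p = 0.00811), and RNF146, a ubiquitin ligase of the Wnt pathway, from -0.51 to -3.25, CLK4, a splicing kinase, from -0.71 to -3.38, and FAM200C from -0.81 to -3.50. AMDHD1 went from 0.94 to 3.40 and H2AC8 and C1orf162 from 1.03 and 0.80 to 3.23 and 3.00. EGR1 went from -2.54 to -0.32, a difference of 2.22 ± 0.63 (SE, limma adjusted p = 0.0377), against an untreated level that itself declined, from 11.43 ± 0.55 at 1 h to 8.75 ± 0.27 at 6 h (mean ± SD of 3 arrays), while the level under compound A was 7.21 ± 0.33 and 8.57 ± 0.21. This count rested on few hours, with 884 genes left without 1 h, 3 without 2 h, 0 by limma without 5 h (4804 at an unadjusted p under 0.05) and 841 without 6 h. Rises made up 23.9% of the calls as deposited, 14.3% with arrays centred on their median, 35.3% with arrays quantile-normalized again, 1.17% with poly-A and 1.23% with hybridisation spike-in scaling.

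**Figure D3:**
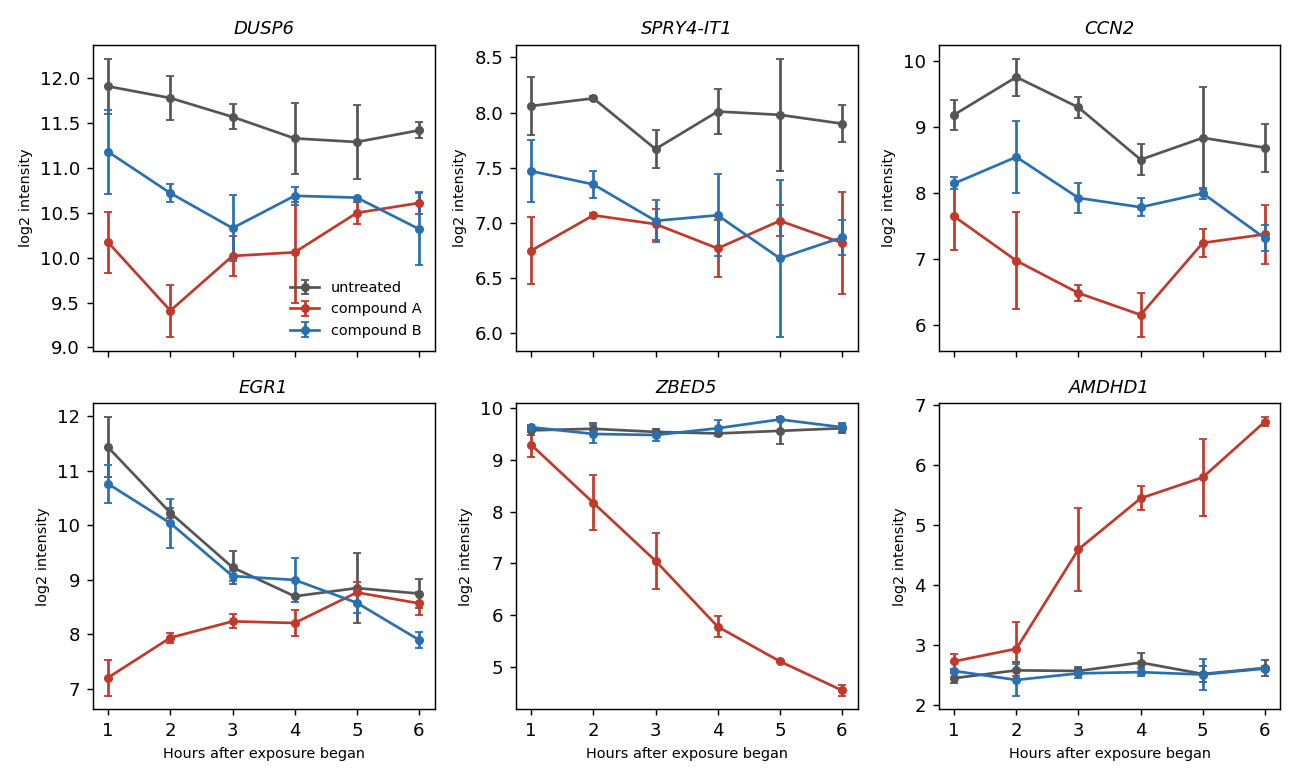
Log2 intensity (y axis) against hours after exposure began for 6 genes in untreated cells (grey), compound A (red) and compound B (blue), as mean ± SD of 2 or 3 arrays. DUSP6, SPRY4-IT1 and CCN2 lay below untreated cells under both compounds, EGR1 in untreated cells declined from 11.43 at 1 h to 8.75 at 6 h, and ZBED5 fell to 4.55 and AMDHD1 rose to 6.73 at 6 h under compound A.

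Compound B was compared with untreated cells in the same way, and far fewer genes passed. Its deepest falls were in CCN2, in the ERK phosphatases DUSP6 and DUSP5, in SPRY4-IT1, a noncoding RNA of the SPRY4 locus, and in MAFF, a small basic leucine zipper factor. CCN2 fell by 1.11 ± 0.16 on the log2 scale (SE, n = 6 hours, limma adjusted p = 0.023), from 9.03 ± 0.40 to 7.91 ± 0.40 (mean ± SD of 6 hours), and was lower at each hour, by 0.96 to 1.26. SPRY4-IT1 fell by 0.94 ± 0.10 (SE, limma adjusted p = 0.00499) and DUSP6 by 0.95 ± 0.17 (SE, limma adjusted p = 0.04996). MAFF fell by 0.91 ± 0.15, DUSP5 by 0.82 ± 0.14, the immediate early phosphatase DUSP2 by 0.75 ± 0.13, the chemokine receptor CCR1 by 0.66 ± 0.12 and the T-box factor TBX2 by 0.57 ± 0.09. The largest rises were in the transporter pseudogene ABCC6P1 with 0.65 ± 0.09 (SE, limma adjusted p = 0.023), the histone gene H2AC6 with 0.58 ± 0.08, TTC14 with 0.48 ± 0.07, the protease CTSK with 0.47 ± 0.08, CTC-338M12.4 with 0.39 ± 0.05, COPG2IT1 with 0.34 ± 0.06, EPB41L5 with 0.32 ± 0.06 and the DNA repair gene RDM1 with 0.29 ± 0.05.

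In all, 26 genes passed for compound B, 10 higher and 16 lower, and 1805 had an unadjusted p under 0.05. The spread shared with compound A, whose effect changed over time, limits this count. SPRY4, for one, changed by -0.46 to -1.29 at the 6 single hours under compound B and was not among the 26. ACTB and GAPDH changed by -0.07 ± 0.04 and 0.01 ± 0.03 (SE, limma adjusted p = 0.605 and 0.988). Of the 3 compound B arrays that stood apart from the others, 2 were the 4 h group and 1 was array 2 at 5 h. Their second principal component was 46.45, -28.65 and 29.40, against -9.85 to 5.94 in the other 42 arrays. The 3' minus 5' log2 difference of ACTB, a control of RNA integrity, was 1.02, 0.52 and 0.19 in them, against -0.08 to 0.41 in the others. Without these arrays 3 genes passed, SPRY4-IT1 and CTC-338M12.4 among them with changes of -0.83 and 0.32, and CCN2 then had a change of -1.17 with an adjusted p of 0.0757. The count was also 3 without the day adjustment, 5 without 2 h, 1 without 3 h, 2 without 5 h, 3 without 6 h, and 0 by limma without 4 h (1566 at an unadjusted p under 0.05). Within hybridisation day D 41 genes passed, and within day C 0 passed by limma, with 1729 at an unadjusted p under 0.05. CCN2 changed by -1.18 on both days. These fits took single arrays as the repeats and held 2 matched hours each, with 1 residual degree of freedom on day C. Their counts are therefore not comparable with the 26 over all hours. With poly-A scaling 27 genes were lower and 0 higher, and with hybridisation spike-in scaling 9 were lower and 0 higher, so that the named rises did not pass under either.

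The ERK feedback genes were the list most clearly lowered by compound B. Of 17 measured genes 3 fell, DUSP5, DUSP6 and EPHA2, with 11 falls adjusted over the list alone (camera adjusted p = 2.48e-13, adjusted p = 0.00791 with an estimated correlation). The list mean was -0.37 over all hours, between -0.32 and -0.43 at each hour, and -0.35 and -0.41 within hybridisation days C and D. EPHA2 fell by 0.44 ± 0.06 (SE, limma adjusted p = 0.0133). Of 27 immediate early genes 3 fell, CCN2, DUSP2 and the orphan receptor NR4A2 with 0.53 ± 0.09, and 6 fell adjusted over the list alone (camera adjusted p = 8.71e-10, adjusted p = 0.0823 with an estimated correlation). None of 32 short-lived transcripts passed over all genes, and 4 fell adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.131 with an estimated correlation), where MYC had a change of -0.70 ± 0.13 (limma adjusted p = 0.0599), PIM1 -0.36 and ID3 -0.50. TGF-beta targets and Wnt and YAP targets had 1 fall each, CCN2 in both, with 2 and 1 adjusted over the list alone (camera adjusted p = 6.52e-05 and 0.00285, adjusted p = 0.0855 and 0.0614 with an estimated correlation). Within them SNAI2 had a change of -0.50, AMOTL2 of -0.37 and AXIN2 of 0.19, none past the threshold.

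Lists of ribosome biogenesis, E2F, NF-kB, ATF4, histone and mitotic genes passed under compound B with at most 1 member past the threshold over all genes. In 25 ribosome biogenesis genes 0 passed over all genes and 2 fell adjusted over the list alone (camera adjusted p = 3.05e-09, adjusted p = 0.0683 with an estimated correlation). The smallest p-values were for NIP7 at -0.40 ± 0.10 (SE), UTP20 at -0.25 ± 0.07 and LYAR at -0.22 ± 0.08. In 33 G1/S and E2F targets 0 passed by either adjustment (camera adjusted p = 0.000634, adjusted p = 0.0817 with an estimated correlation). The values were those of the helicase genes MCM7 and MCM2 at -0.23 and -0.18 and UNG at -0.24. In 19 NF-kB targets 0 passed and 2 fell adjusted over the list alone (camera adjusted p = 0.00282, adjusted p = 0.162 with an estimated correlation). TNFAIP3 stood at -0.36, IRF1 at -0.35 and RELB at -0.24. In 31 ATF4 pathway genes 0 passed, and 2 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.032, adjusted p = 0.344 with an estimated correlation). CTH stood at 0.34, NUPR1 at 0.26 and SLC7A5 at -0.23. Of 14 histone genes 1 rose, H2AC6, and 6 rose adjusted over the list alone (camera adjusted p = 2.4e-08, adjusted p = 0.0817 with an estimated correlation). H2BC4 and H2BC5, which did not pass over all genes, stood at 0.40 and 0.38, and the list median of 0.20 was 0.02 with poly-A scaling. Of 42 mitotic genes 35 lay above untreated cells as deposited and 0 passed (camera adjusted p = 0.00208, adjusted p = 0.662 with an estimated correlation). CDC25C stood at 0.38, CDCA3 at 0.19 and PTTG1 at 0.13, and their median of 0.08 turned to -0.09 with poly-A scaling. The 27 p53 targets did not pass (camera adjusted p = 0.903), with PMAIP1 at -0.43, DDB2 at 0.18 and TP53I3 at 0.12, and the remaining 15 lists had adjusted p-values from 0.232 to 1.

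Hour by hour, compound B lowered 7 genes at 1 h and raised none, led by DUSP5 with a fall of 1.34 ± 0.21 (SE, 3 arrays against 3, limma adjusted p = 0.00328), CCN2 with 0.96 ± 0.15 and HES1 with 0.89 ± 0.16. At 6 h 188 genes passed, 84 higher and 104 lower. The deepest falls were in SPRY4, a feedback inhibitor of ERK signalling, with 1.28 ± 0.10 (limma adjusted p = 3.52e-09), MAFF with 1.21 ± 0.26 and CCN2 with 1.05 ± 0.14, and the highest rises in APOLD1 with 1.30 ± 0.17, LMOD1 with 1.11 ± 0.19 and ATOSA with 0.99 ± 0.14. Counts between these hours were 7 at 2 h, 11 at 3 h, 13 at 4 h and 17 at 5 h, with 0, 0, 7 and 5 genes higher. Again the p-values cover the spread between arrays only. At 3 h and at 4 h the arrays of compound B and untreated cells shared no hybridisation day. The counts at those hours therefore rest on additive day offsets fitted over all groups. Of the 13 calls at 4 h, 53.8% were higher as deposited, against 40.0% with arrays centred on their median, 10.0% with quantile normalization repeated and 0 of 2 calls with poly-A scaling, and the corresponding shares at 6 h were 44.7% as deposited and 4.76% with poly-A scaling. The 4 h count was 1616 without compound B array 1 and 4453 without compound B array 2 of that hour, both among the 3 arrays that stood apart, and without all 3 of them 635 genes passed at 6 h. The 6 h count was 71, 107 and 49 without untreated arrays 1, 2 and 3 of that hour, and 53, 68 and 118 without compound B arrays 1, 2 and 3. Without untreated array 1 it was 1 at 1 h, 0 by limma at 2 h (458 at an unadjusted p under 0.05), 7 at 3 h, 2 at 4 h and 1 at 5 h, and without untreated array 2 it was 3 at 4 h and 5 at 5 h. Without compound B array 1 it was 2 at 2 h, 7 at 3 h and 32 at 5 h, and without compound B array 2 it was 0 by limma at 2 h (411 unadjusted) and 3 at 5 h. Between the first and last 3 hours the effect of compound B differed for 0 genes by limma, with 1216 at an unadjusted p under 0.05 and a smallest adjusted p of 0.65. The smallest p-values, which did not pass, were for MBNL2, a splicing regulator, with a difference of 0.55 ± 0.09, and for the coagulation factor F5 with 0.42 ± 0.08.

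The compounds were then compared with each other at matched hours. Of the 8 largest falls relative to compound B, ZNF92, PNRC1, DUSP1, ZNF256, EXOC8 and MSL2 were also among the 8 largest relative to untreated cells, and ZBED5 and ZNF684 were not, where both comparisons used the same compound A arrays. ZNF92 differed by -3.28 ± 0.28 (log2 change, SE, n = 6 hours, limma adjusted p = 7.14e-06), PNRC1 by -3.24, DUSP1 by -3.19 with 1 of 2 other probe sets opposite, ZNF256 by -3.18, EXOC8 by -3.04, MSL2 by -3.001, ZBED5 by -2.96 with 1 of 2 other probe sets opposite, and ZNF684 by -2.96. Higher under compound A were AMDHD1 with 2.19 ± 0.47 (SE, limma adjusted p = 0.00333), H2AC8 with 1.78, C1orf162 with 1.77, RFPL3S with 1.70, SCG5 with 1.25, H3C2 with 1.24, LOC389834 with 1.08 and RPPH1, the RNA component of ribonuclease P, with 1.04 ± 0.09 (SE, limma adjusted p = 4.86e-06). In total 10025 genes differed, 6653 higher and 3372 lower under compound A, and 805 were lower and 14 higher by more than 2-fold. ACTB and GAPDH differed by 0.03 ± 0.04 and 0.02 ± 0.03 (SE, limma adjusted p = 0.502 and 0.643). The share of higher genes was 66.4% as deposited, 54.6% with arrays centred on their median, 5.47% with hybridisation spike-in scaling and 0.51% with poly-A scaling, where the spike-ins read 0.35 higher under compound A than under compound B in 6 of 6 hours, and 0.31 and 0.13 higher within days C and D. Within days C and D 129 and 1086 genes passed, in fits that took single arrays as the repeats and held 2 matched hours each. Correlations with the log2 changes over all days were 0.974 and 0.904, partly built in because the same arrays enter both. Without the 4 and 5 h groups 2003 genes passed.

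Short-lived transcripts separated the compounds most, with 31 of 32 lower under compound A than under compound B (camera adjusted p = 4.38e-24, adjusted p = 0.0136 with an estimated correlation). BHLHE40 and ID1 differed by -2.29 ± 0.16 and -2.27 ± 0.14 (log2 change, SE) and the regulator IER5 by -2.22 ± 0.18. Immediate early genes were lower in 16 of 27, 17 adjusted over the list alone (camera adjusted p = 1.67e-11, adjusted p = 0.0817 with an estimated correlation). TRIB1 stood at -2.34. The ERK feedback genes were split, 7 lower and 3 higher of 17, with 8 and 3 adjusted over the list alone (camera adjusted p = 0.00659, adjusted p = 0.105 with an estimated correlation). SPRY1 and DUSP5 differed by -1.42 ± 0.13 and -1.12 ± 0.14. The ETS factor ETV4 was higher by 0.57 ± 0.12 (SE, limma adjusted p = 0.00283). The ATF4 pathway had 17 lower and 5 higher of 31, with 19 lower adjusted over the list alone (camera adjusted p = 1.43e-07, adjusted p = 0.0481 with an estimated correlation), including DDIT4 at -2.05, CHAC1 at -1.84 and DDIT3 at -1.18. Wnt and YAP targets had 8 lower and 2 higher of 16 (camera adjusted p = 0.000416, adjusted p = 0.0339 with an estimated correlation). AXIN2 stood at -1.11, LATS2, a Hippo kinase, at -0.79 and ZNRF3 at -0.60.

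Mitotic genes were lower under compound A than under compound B in 23 of 42 cases and higher in 2, with 24 and 3 adjusted over the list alone (camera adjusted p = 1.43e-07, adjusted p = 0.465 with an estimated correlation). HJURP stood at -1.61 ± 0.28 (log2 change, SE), KIF23 at -0.99 ± 0.20 and the mitotic kinase CDK1 at -0.30 ± 0.06. The p53 targets had 16 lower and 6 higher of 27, with 17 lower adjusted over the list alone (camera adjusted p = 1.65e-06, adjusted p = 0.0817 with an estimated correlation). PLK2 stood at -2.66, GDF15 at -1.37 and REV3L at -0.93. CDK and cyclin genes had 14 lower and 2 higher of 24 (camera adjusted p = 1.09e-05, adjusted p = 0.105 with an estimated correlation). CCNT2 stood at -1.65, CDKN1B at -1.002 and CCNE2 at -0.86. TGF-beta targets had 11 lower and 3 higher of 17, with 5 higher adjusted over the list alone (camera adjusted p = 1.8e-05, adjusted p = 0.0817 with an estimated correlation). TGIF1 stood at -1.82, with 1 of its 2 other probe sets opposite. FOXO and PI3K-responsive genes had 8 lower and 4 higher of 22, with 9 lower adjusted over the list alone (camera adjusted p = 0.0039, adjusted p = 0.0817 with an estimated correlation). BCL6 stood at -2.03 and CITED2 at -2.01, where 1 of 2 other probe sets was opposite. Hypoxia targets had 8 lower and 3 higher of 19 with a mean of -0.29 and a median of 0.02 (camera adjusted p = 0.0253, adjusted p = 0.0817 with an estimated correlation). ADM stood at -1.75, ANKRD37 at -1.30 and VEGFA at -0.62. G1/S and E2F targets had 15 lower and 10 higher of 33 (camera adjusted p = 0.0465, adjusted p = 0.264 with an estimated correlation). SLBP, which binds histone mRNA, stood at -0.48 and UNG at -0.40. Histone genes, 6 higher and 4 lower of 14, did not separate the compounds (camera adjusted p = 0.958), with 2 higher and 8 lower under poly-A scaling, and ribosome biogenesis genes had 7 higher and 8 lower of 25.

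By hour the compounds differed in 197 genes at 1 h, 1124 at 2 h, 3002 at 3 h, 5184 at 4 h, 5366 at 5 h and 9342 at 6 h, with 5, 143, 956, 2457, 2270 and 5517 genes higher under compound A, by p-values that cover the spread between arrays only. At 1 h and at 6 h the arrays of the 2 compounds shared no hybridisation day. The counts at those hours therefore rest on additive day offsets fitted over all groups. Without compound A array 2 the count was 130 at 1 h and 623 at 2 h, without compound B array 2 it was 714 at 2 h, and without compound A array 1 it was 2670 at 4 h. Genes higher made up 31.8%, 47.4%, 42.3% and 59.1% of the calls from 3 to 6 h as deposited, 18.9%, 33.6%, 29.8% and 46.9% with arrays centred on their median, and 0.839%, 0.547%, 0.487% and 0.268% with poly-A scaling, and at 2 h 12.7% fell to 0.102% with that scaling. Repeated quantile normalization gave 44.4% at 3 h and 54.1% at 5 h. The difference between the compounds changed between the first and last 3 hours for 3509 genes, upward in 1091 and downward in 2418. ZBED5 changed by -3.38 ± 0.56 (log2, SE, limma adjusted p = 0.00339), RNF146 by -2.98 ± 0.35, CLK4 by -2.95 ± 0.49 and FAM200C by -2.89 ± 0.44. AMDHD1 changed by 2.59 ± 0.50, LINC00326 by 2.44 ± 0.37, EGR1 by 2.29 ± 0.63 and the YAP target CCN1 by 2.22 ± 0.39. CCN1 stood at -2.12 over the first 3 hours and -0.04 over the last 3 under compound A against untreated cells, and at -0.59 and -0.72 under compound B. The count was 1645 without 1 h, 1367 without 2 h, 1840 without 5 h and 2293 without 6 h, and rises made up 31.1% of the calls as deposited, 21.2% with arrays centred on their median, 43.2% with quantile normalization repeated, 0.548% with poly-A and 2.53% with hybridisation spike-in scaling.

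The genes called for each compound were then compared. Of the 16 genes lower under compound B, SPRY4-IT1, CCN2, DUSP6 and DUSP5 among them, 15 were also lower under compound A, and of the 10 higher under compound B 7 were also higher. Independent lists of these sizes would share 2.81 and 3.66, but the shared untreated arrays can also raise the overlap, so these are not the numbers for no common effect. None of the 26 moved in opposite directions. Both comparisons used the same untreated arrays, so across genes the correlation of their log2 changes, 0.261, was set beside 0.501 in 100 simulations of unchanged groups against those controls. The simulated value is fixed near 0.50 by the shared controls and equal spreads. Changes under compound A, absent from the simulation, can also lower the observed correlation. These correlations therefore cannot show or exclude a common effect. The observed covariance was 0.0106 and the simulated one 0.00417, a difference of 0.00646. The simulated spread included changes over time in the effect of compound A, so the simulated covariance may be too high for unchanged groups. With the untreated hours split between the compounds, the correlations were 0.127 and 0.257 and the covariances 0.0053 and 0.0145.

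Time itself was tested in untreated cells, as a linear slope per hour. EGR3 and EGR1, immediate early transcription factors, had slopes of -0.56 ± 0.08 and -0.52 ± 0.08 log2 units per hour (SE, limma adjusted p = 0.0258 and 0.0298). EGR3 stood at 7.46 ± 0.51 at 1 h and 4.67 ± 0.12 at 6 h, and FOS, which did not pass, at 7.05 ± 0.45 and 5.27 ± 0.15 (mean ± SD of 3 arrays). These 2 genes were the calls among 629 with an unadjusted p under 0.05. The count was 1 without 1 h, where neither EGR3 nor EGR1 passed, 0 by limma without 2 h (397 at an unadjusted p under 0.05) or without 5 h (481), 2 without 4 h with 1 of the named genes among them, 4 without 6 h, and 8 with poly-A scaling.

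The day of hybridisation was tested across all groups, since the series set out to evaluate it. MAB21L2, CCN2, CCR1 and NFIL3 had the largest day effects (limma F of 38.8, 34.6, 28.6 and 26.9, adjusted p = 3.66e-06, 7.13e-06, 3.99e-05 and 6.00e-05). Compared with day A, CCN2 read 0.98 higher on day C and NFIL3 0.68 higher, while MAB21L2 and CCR1 read 0.74 and 0.79 higher on day B. A day effect passed for 269 of the 19775 genes, and 3007 had an unadjusted p under 0.05. The median range between days was 0.14 on the log2 scale over all genes and 0.41 over the 269. The count was 976 without the 3 compound B arrays that stood apart, and 28 genes passed when hour and compound terms replaced the 18 groups. CCN2 and CCR1 also fell under compound B, and CCN2 did so by 1.18 within both day C and day D.

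**Figure D4:**
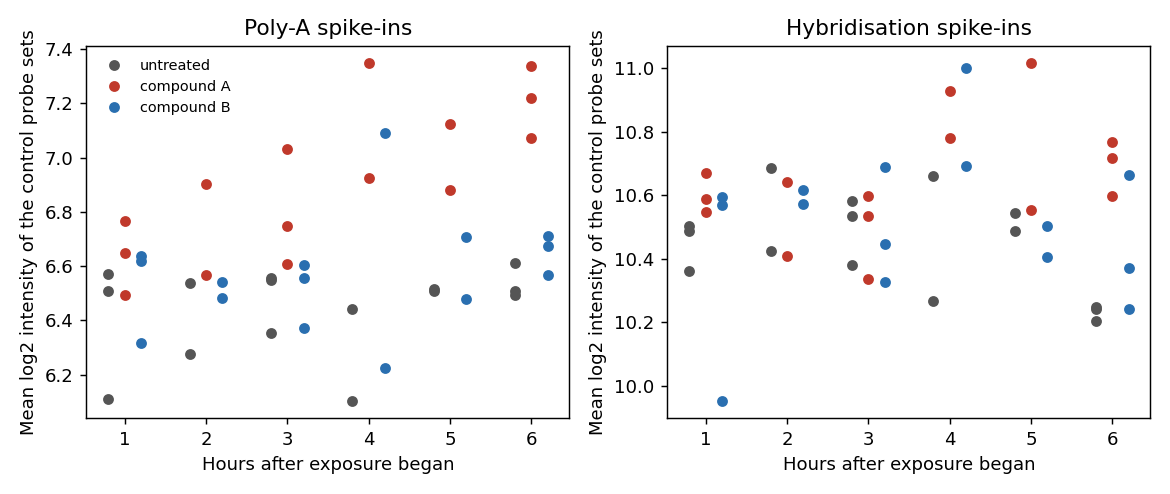
Mean log2 intensity of the poly-A spike-in probe sets (left) and the hybridisation spike-in probe sets (right) on each of the 45 arrays against hours after exposure began, in untreated cells (grey), compound A (red) and compound B (blue), where each point is 1 array. Averaged over hours the poly-A spike-ins stood at 6.44 in untreated cells, 6.92 under compound A and 6.57 under compound B, and the hybridisation spike-ins at 10.5, 10.7 and 10.5.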

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

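The random regroupings and the comparison of the first with the last 3 hours were fixed before the results were seen, and the spike-in comparisons and the tests of explanations in this part were chosen only after the result was seen.

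Among the control probe sets, the poly-A spike-ins read 0.48 higher under compound A than in untreated cells (0.484, SD 0.243, n = 6 hours, higher in 6 of 6, exact sign-flip p = 0.0312, the smallest that 6 hours can give, and 0.0625 adjusted over 6 comparisons), and 0.52 ± 0.08 (SE) higher with the day as a block. The hybridisation spike-ins read 0.21 higher (4 of 6 hours, exact p = 0.125), and under compound B the poly-A spike-ins read 0.14 higher (6 of 6 hours, exact p = 0.0312, within day C -0.02). The difference between the first and last 3 hours passed for 2569 genes under compound A and for 3509 genes between the compounds. Its named values against untreated cells were 2.46 for AMDHD1, 2.22 for EGR1, 2.20 for H2AC8, 2.20 for C1orf162, -2.95 for ZBED5, -2.74 for RNF146, -2.68 for FAM200C and -2.67 for CLK4. Between the compounds they were 2.59 for AMDHD1, 2.44 for LINC00326, 2.29 for EGR1, 2.22 for CCN1, -3.38 for ZBED5, -2.98 for RNF146, -2.95 for CLK4 and -2.89 for FAM200C.

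Rises outnumbered falls among the genes called under compound A, 7238 to 3478. A candidate explanation is a common scale that lifts all genes of an array when mRNA is a smaller part of the total RNA, and the poly-A spike-ins did read higher in 6 of 6 hours. The 0.175% of rises after scaling to them is no test of it, since that scaling moves all genes alike by more than the median rise. Rises from dim probe sets alone are argued against by 3734 rises among brighter and 3504 among dimmer genes (2915 and 1943 with arrays centred on their median), but whether the excess comes from dim ones stays open, with 55.9% rises among brighter genes as deposited and 47.8% centred, against 86.7% and 76.2% among dimmer genes. Whether the same amount of spike-in was added to each sample stays open too.

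Of the compound B arrays, both at 4 h and the second at 5 h stood apart. RNA integrity or amplification length may be involved, since 2 of the 3 arrays lay outside the range of the other 42 in the ACTB 3' minus 5' difference, but the array at 5 h lay inside it. A compound A array under a swapped label is argued against, because in 3 of 3 the short-lived mean, at least 8.54, was above the highest compound A array at 7.85. The ERK feedback mean, at most 7.84, was below the lowest untreated array at 7.93. That list was the one most clearly lowered by compound B in these data, these arrays included, so a swapped untreated array stays open. The hybridisation day is argued against too, since the other 26 arrays of days C and D reached an absolute second component of 6.18 at most. What lowered the integrity, if it was lowered, stays open.

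Day effects were concentrated in fast-responding genes, with 15 of 68 immediate early, ERK feedback and short-lived genes past the day threshold (22.1%, against a median of 1.47% and a highest value of 7.35% in 1000 random lists of matched brightness). The 3 compound B arrays are argued against as the source, since without them 976 genes passed, 25 of the 68 (36.8%) among them. Hybridisation, washing or scanning stays open, since 22.1% describes which genes differed and does not tell these steps from the cells. Cultures or extractions handled separately for each day may be a source too, which was not tested.

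In random regroupings, the real grouping was counted among those that called as many genes as reported. For compound A over 6 hours this was 1 of 100 (highest other 8703), for compound B 2 of 100 (highest other 3913), for compound A against compound B 2 of 100 (highest other 10031), and for the day 1 of 100 (highest other 1). For compound B a single other regrouping reached the 26 calls of the treatment, and it called 3913, which points to a structure of the samples along that 1 regrouping, whose cause was not tested. For the difference between first and last 3 hours and for single hours at 1, 3 and 6 h the 10 splits are too few to say more, with 2569, 0 and 3509 calls for the former (highest other 0), and 1 of 10 for each single hour with a highest other of 0. For the difference under compound B all 10 of 10 had 0 calls by limma, with 1216 genes at an unadjusted p under 0.05 as reported and 1 call with single arrays and the group as a random block.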

How the results depend on the processing

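The alternatives that leave out the 3 compound B arrays or the 4 and 5 h groups, or scale to spike-ins, the median centring at single hours, and the split of the pairing check by hour with the best match of each array were chosen only after the results were seen; all others were planned.

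Of 81 list tests 37 passed, and 8 with an estimated correlation. The count was 35 without day adjustment, 29 with brighter genes only, 34 to 37 with 1 hour left out and 32 without the 3 compound B arrays. Among named genes, poly-A scaling turned BIRC5 under compound A to -0.32, H2BC5 to -0.0718 and H1-2 to -0.0277, and hybridisation spike-in scaling turned BIRC5 to -0.0128.

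Compound A over 6 hours (10716 calls) gave 6899 among brighter genes only, 23616 with all probe sets, 3634 and 3210 within days C and D, 4425 without 4 and 5 h, 18877 with poly-A and 4692 with hybridisation spike-in scaling, and 7662 to 11367 with 1 hour left out. Without day adjustment 10305 of the 10716 genes were shared. Compound A against compound B (10025) gave 6516 among brighter genes, 22131 with all probe sets, 129 and 1086 within days C and D, 2003 without 4 and 5 h, 3273 with hybridisation spike-in scaling, and 6738 to 10870 with 1 hour left out.

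Compound B over 6 hours (26) gave 3 without day adjustment, 161 with single arrays and the group as a random block, 66 among brighter genes, 46 with all probe sets, 46 with the mean of a gene's probe sets, 41 within day D, 3 without the 3 compound B arrays and 9 with hybridisation spike-in scaling. By limma it gave 0 within day C (1729 at an unadjusted p under 0.05) and 0 without 4 and 5 h (1076). With 1 hour left out it ran from 0 (4 h, 1566 unadjusted) to 27 (1 h), with 5 without 2 h, 1 without 3 h, 2 without 5 h and 3 without 6 h.

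The difference between first and last 3 hours under compound A (2569) gave 4409 without day adjustment, 5723 with single arrays and the group as a random block, 4163 with all probe sets, 4190 with poly-A and 4068 with hybridisation spike-in scaling. With 1 hour left out it ran from 0 by limma (5 h, 4804 unadjusted) to 3642 (4 h), with 884 without 1 h, 3 without 2 h and 841 without 6 h. Between the compounds (3509) it gave 5857 with all probe sets and 8576 with poly-A scaling, and 1367 (2 h) to 3844 (4 h) with 1 hour left out, with 1645 without 1 h, 1840 without 5 h and 2293 without 6 h. Under compound B (0 by limma, 1216 unadjusted) it gave 1 with single arrays and the group as a random block. The slope in untreated cells (2) gave 18 with that block, 6 with all probe sets, 4 with the mean of a gene's probe sets, 8 with poly-A scaling, 0 by limma with an intensity trend (611 unadjusted) and 0 among brighter genes (450). With 1 hour left out it ran from 0 (2 h, 397 unadjusted, and 5 h, 481) to 4 (6 h), with 1 without 1 h, which was neither EGR3 nor EGR1.

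Compound A at single hours gave, with all probe sets, 778, 2454, 7383, 7707, 11644 and 20314 calls from 1 to 6 h. It gave 204 at 1 h without a day term, 1278 at 4 h with only the 3 groups of that hour, 6370 at 6 h among brighter genes, 2278 at 2 h without the 3 compound B arrays, and 11828 at 4 h and 15985 at 6 h with poly-A scaling. With 1 array left out the counts ran from 202 (compound A array 2) to 277 at 1 h, 739 (compound A array 2) to 1129 at 2 h, 2353 (compound A array 3) to 3842 at 3 h, 2235 (untreated array 1) to 3541 at 4 h, 3630 (untreated array 1) to 5001 at 5 h and 6650 to 9360 at 6 h. The 2 h count was also 907 without untreated array 2 and the 4 h count 2764 without compound A array 1.

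Compound B at single hours gave from 1 to 5 h, without a day term, 4, 0 (380 unadjusted by limma), 5, 0 (1546) and 4 calls, and with only the 3 groups of the hour 3, 0 (594), 6, 0 (272) and 0 (1566). With the day as a random block it gave 3, 0 (418), 5 and 0 (1581) from 1 to 4 h. Brighter genes gave 17, 25, 41 and 314 from 3 to 6 h, all probe sets 3 at 2 h, and an intensity trend 22 at 4 h. Poly-A scaling gave 4, 1, 3, 2, 1 and 21 from 1 to 6 h, and leaving out the 3 compound B arrays 24 at 3 h, 5 at 5 h and 635 at 6 h. With 1 array left out the counts ran from 1 (untreated array 1) to 6 at 1 h, 0 (untreated array 1, 458 unadjusted by limma, and compound B array 2, 411) to 5 at 2 h with 2 without compound B array 1, and 7 (untreated array 1 or compound B array 1) to 10 at 3 h. At 4 h they were 2 and 3 without untreated arrays 1 and 2, and 1616 and 4453 without compound B arrays 1 and 2. At 5 h they were 1 and 5 without untreated arrays 1 and 2, and 32 and 3 without compound B arrays 1 and 2. At 6 h they were 71, 107 and 49 without untreated arrays 1, 2 and 3, and 53, 68 and 118 without compound B arrays 1, 2 and 3.

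Compound A against compound B at single hours gave 432, 2056, 5733, 9831, 10186 and 19972 calls with all probe sets, 6018 at 6 h among brighter genes, 1321 at 4 h with only the 3 groups of that hour and 79 at 1 h with poly-A scaling. With 1 array left out the counts ran from 130 (compound A array 2) to 175 at 1 h, 623 (compound A array 2) to 937 at 2 h, with 714 without compound B array 2, 2244 to 2609 at 3 h, 2670 (compound A array 1) to 7023 at 4 h, 3709 to 4376 at 5 h and 6778 to 8919 at 6 h. The day effect (269) gave 28 with hour and compound terms in place of the groups and 976 without the 3 compound B arrays.

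Replicate numbers did not pair the arrays by the rule that all pairs correlate at over 0.1 in their deviations from the group means: 12 of 45 pairs of equal number did (-0.145 to 0.325, median 0.046). Of these, 8 were among the 10 pairs of compound B and untreated arrays at 3 to 6 h (0.09 to 0.211). At 2, 4 and 5 h, with 2 arrays per group, both pairs give the same value by construction, so these counts hold each such correlation 2 times. As a hint from the data and not from the design, at 3 and 6 h 6 of 6 arrays correlated best with their own number for each compound against untreated cells, and at 1 h 4 of 6 did. Between compound A and compound B 2 of 6 did at 1 h, 0 of 6 at 3 h and 4 of 6 at 6 h, so the hint does not hold between the compounds. With replicate number as a block in a pairing check, the slope gave 1 call, and compound B at 3 to 6 h gave 18, 42, 38 and 320. The cause of these movements was not tested.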

Other observations

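The zinc finger family, the largest group of DNA-binding repressors, was lowered more than genes of equal brightness under compound A. Of 502 ZNF genes 290 fell and 66 rose as deposited, with a median of -0.35, and with arrays centred on their median, scaled to poly-A spike-ins or scaled to hybridisation spike-ins 296, 497 and 326 fell and 39, 1 and 2 rose. Of 10 SRSF splicing factor genes 7 fell, and of 30 Mediator genes 16 fell and 8 rose. Under compound B 1 ZNF gene rose and none of the SRSF or Mediator genes passed by limma. Oxidative phosphorylation genes, with stable transcripts, had 71 rises and 2 falls of 93 under compound A as deposited, 50 and 3 with median centring, but 0 and 90 with poly-A and 0 and 5 with hybridisation spike-in scaling. Replication-dependent histone genes had 26 rises and 0 falls of 39 as deposited and 25 and 0 centred, but 2 and 23 with poly-A and 7 and 1 with hybridisation spike-in scaling. Whether the histone signals, after amplification from the 3' end, follow the transcript levels was not tested.

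All tests in this part were chosen only after the result was seen.

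A candidate explanation for the fall of short-lived transcripts under compound A is reduced synthesis by RNA polymerase II, since transcripts with a fast turnover would be lost first. Their mean was already -1.17 at 1 h, with 24 of 32 past the threshold, against a median of 0.00 and a lowest value of -0.21 in 1000 random lists of matched brightness. The list was already known to fall over all hours, so this shows an early fall and is no separate test of reduced synthesis. Lists matched for brightness alone cannot tell turnover from other traits of these genes. RPPH1, a product of RNA polymerase III, rose by 0.848 (SE 0.0851, limma adjusted p = 2.02e-05, higher in 6 of 6 hours), and by 0.32 with poly-A scaling, but as a single gene named because it was high it is no test of whether polymerase III products escape the fall. Faster decay of these transcripts was not tested, and the compound's target is not known from these data.

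The median of the zinc finger genes, -0.35, lay below the lowest of 1000 random lists, 0.08, where the median list had 0.11. The family was taken up after ZNF genes had been seen among the deepest falls. These values therefore describe the fall and are no test of a family effect. A family effect and short transcript half-life, which was not measured here, both stay open.

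Immediate early genes may recover in part under compound A, with a difference of 0.605 between the last and first 3 hours (camera adjusted p = 0.00106, adjusted p = 0.755 with an estimated correlation), so the question stays open, also because EGR1 declined in untreated cells. Mitotic genes may rise late under compound B, with a list difference of 0.30 as deposited (camera adjusted p = 5.24e-16, adjusted p = 0.755 with an estimated correlation), and this stays open as well, since the call was lost with the estimated correlation.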
